A study of Mus musculus with 3 samples.

How the data were processed

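Polyadenylated RNA was sequenced from 3 cultures of mouse embryonic stem cells (ESCs), with 1 library from each: a wildtype clone, a DAXX knockout clone and an ATRX knockout clone. The labels describe the clones as male, isogenic, of C57BL/6x129sV background and made by CRISPR targeting. Per the labels' protocols, the cells grew with serum and leukaemia inhibitory factor, had been moved off irradiated feeder cells onto gelatin, and gave column-purified total RNA from which TruSeq libraries were made. The position of each targeted change within its gene was not given in the sources used here.

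The values used are the read counts as deposited, not normalised, with 1 table per library in the layout that the idxstats command of SAMtools writes: a reference sequence, its length and the reads aligned to it. Per the submitters' processing notes, Bowtie 1.1.2, SAMtools and the mouse build GRCm38.p4 were used. The alignment settings, the treatment of reads with several equally good positions, the use of strand and the annotation release were not given in the sources used here. Each table held 50407 named sequences, of which 48843 were transcripts with an Ensembl identifier and a gene symbol and 1564 were repeat consensus sequences. Because reads were aligned to transcripts and not to the genome, reads from introns and from unannotated sequence do not enter the counts, and transcripts of 1 gene compete for the same reads. How such reads were placed was examined on pairs of transcripts with identical sequence, a test chosen after the data were seen because nested transcripts had not decided it. Among pairs with at least 20 reads, equal counts were seen in 1 of 34 pairs in the wildtype library, 0 of 31 in the DAXX knockout library and 2 of 32 in the ATRX knockout library. The chi-square per degree of freedom against an even split was 1.05, 0.668 and 0.986, as when each read is placed once, at random, on 1 of its equal positions. Counts of a gene's transcripts were therefore summed, which gave 24006 gene symbols, 13250 of them with 1 transcript. Genes with near-identical copies elsewhere can exchange reads under such placement and their values are uncertain. Without stated use of strand, a gene cannot be separated from an antisense partner.

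The tables hold 14080945 aligned reads for the wildtype library, 11336399 for the DAXX knockout library and 14097738 for the ATRX knockout library. All named sequences were a transcript or a repeat, with 0 left over, and 145 transcripts carried clone names in place of a gene symbol. Gene positions come from GENCODE M21, on build GRCm38, and were found for 23918 symbols (99.6%). The release may differ from the one used by the submitters.

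Gene counts were scaled by trimmed mean of M values (TMM, edgeR 4.0.16 in R 4.3.3) over the 3 libraries, with factors of 1.04 for wildtype, 0.973 for the DAXX knockout and 0.990 for the ATRX knockout. Repeat counts were scaled by the same effective library sizes. Each genotype had 1 library, which leaves 0 residual degrees of freedom, so no test of genotype was possible and no p-value was computed. A rule of size took its place. A gene was called higher or lower when the whole 95% interval of its fold lay beyond 2-fold, among genes with at least 1 CPM (count scaled by effective library size) in at least 1 of the 2 libraries compared. The interval is the exact conditional binomial (Clopper-Pearson) interval of the 2 counts. It covers counting error only, compares the libraries and not the genotypes, and treats reads as independent although PCR copies are not. A fold against a count of 0 was computed against a floor of 3 counts in that library and is given as a lower bound.

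Gene lists numbered 33. For each list the median log2 fold over members with a mean of at least 1 CPM, with a prior count of 1, was placed among 10000 random lists of the same size. The random lists were drawn with replacement within 10 bins of mean log CPM, and percentiles are given for lists with at least 4 measured members. A list was said to stand apart below percentile 2.5 or above percentile 97.5. These percentiles describe the 3 libraries and are not tests of genotype. The Rhox6 and Rhox9 genes belong to both the trophoblast and the X-linked lists, Rpl10l belongs to both the germline and the ribosomal protein lists, and the pattern for the X-linked list also takes Ssx2ip. Genes shared by both knockouts, and genes of 1 library apart from both others, were counted from the same calls. To show what a shared wildtype library gives by chance, 3 unchanged libraries were simulated 100 times, once with Poisson noise and once with a dispersion estimated from the 3 libraries, which includes any genotype effect.

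The genes named were set by rule. It took Atrx and Daxx, then in each comparison the 10 higher and the 10 lower genes whose interval bound nearest to no change lay farthest from 0, leaving out predicted genes, clone names and pseudogenes. From each list it took up to 4 members past the 2-fold rule, or up to 2 of the most abundant members where none passed, and it took up to 10 genes each from the shared sets and from the sets of 1 library apart. Members of a list that are named without a value come from the calls for that list. The samples, comparisons, scaling, fold rule, gene lists, naming rule and most alternatives were fixed before the data were examined. Repeat families were grouped, chromosome medians were given a limit of 0.1 on the log2 scale, and a cluster on chromosome 4 was chosen after the data were seen.

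The procedure was tested on simulated data drawn from the real means and library sizes, with 200 genes changed by known folds. In the simulated comparison of the DAXX knockout with wildtype, over 12954 genes tested, 0 of 12755 unchanged genes were called. That covers counting noise alone. Unchanged libraries simulated with the dispersion estimated over the 3 libraries gave medians of 71 higher and 65 lower calls in this comparison. Of 40 genes at each fold, 0% were called at 1.5-fold, 2.5% at 2-fold, 92.5% at 3-fold, 87.5% at 4-fold and 97.5% at 8-fold. Changes near 2-fold are therefore mostly missed by the rule. The interval held the true fold for 195 of 200 changed genes. Of random lists, 10 of 200 (5%) stood apart. About this share follows by design, since randomly drawn genes were placed among randomly drawn genes. It does not cover lists whose members vary together.

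The alternatives were total counts and DESeq2 1.42.0 size factors in place of TMM, no filter and a filter of 5 CPM, fold limits of 1.5 and 4, the fold without its interval, the most abundant transcript in place of the sum, counts thinned to the smallest library, a prior count of 5, unmatched random lists, folds centred on each chromosome, and leaving out ribosomal protein and multicopy genes. Leaving out chromosomes 11, 18 and Y, and rescaling the repeat families, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for everything else.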

Results

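Embryonic stem cells (ESCs) are pluripotent cells of the early embryo kept in culture. ATRX, a chromatin remodeller, and DAXX, a histone chaperone, act together in placing the histone variant H3.3 at heterochromatin, telomeres and endogenous retroviruses. The series compared the transcriptomes of male mouse ESCs labelled as knockouts of either gene with those of wildtype cells. There was 1 library for each genotype, so none of the differences has a replicate check. Values in parentheses after a log2 fold are its 95% counting interval.

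The 3 libraries were close in depth. Reads on transcripts numbered 13981915 in wildtype, 11224100 in the DAXX knockout and 13988376 in the ATRX knockout, and 77.01%, 77.3% and 78.9% of all reads were aligned. Genes with at least 1 read numbered 17048, 16024 and 16446. The 10 most abundant genes took 5.67%, 5.87% and 6.14% of the reads, and 12759 genes had a mean of at least 1 in library-scaled counts (CPM). Repeat sequences took 0.703% of aligned reads in wildtype, 0.991% in the DAXX knockout and 0.776% in the ATRX knockout.

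Atrx, on the minus strand of the X chromosome at 105797615 to 105929403 (GRCm38), had 4582 reads in wildtype, 3576 in the DAXX knockout and 1800 in the ATRX knockout. Its level in the ATRX knockout fell by 1.28 on the log2 scale against wildtype (-1.36 to -1.20), while the DAXX knockout gave 0.05 (-0.01 to 0.12). Daxx, on the plus strand of chromosome 17 at 33909414 to 33915590, had 1125, 623 and 972 reads. Its log2 fold was -0.44 (-0.59 to -0.30) in the DAXX knockout, inside the 2-fold limit, and -0.14 (-0.27 to -0.02) in the ATRX knockout. Each targeted gene was thus lowest in the library that carries its name. Transcript remained in both, and its level does not measure the protein left after a change made by CRISPR.

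In the DAXX knockout, 64 genes rose and 204 fell by over 2-fold, out of 13151 tested. Of the genes tested, 13 of 19 of primitive and definitive endoderm fell, 7 of 30 germline genes, 5 of 8 X-linked homeobox and cancer-testis genes, 4 of 11 trophoblast genes and 4 of 5 Y-linked genes. The imprinted noncoding RNAs Meg3 and Rian, from the Dlk1 domain of chromosome 12, went from 237 and 448 reads to 0, falls of at least 59.4-fold and 112-fold. Among repeats, intracisternal A particle (IAP) retroviruses rose by 1.83 (1.78 to 1.89) on the log2 scale and retroviruses related to murine leukaemia virus by 2.17 (2.04 to 2.31). Most genes moved little, with 84.0% of those tested inside 1.5-fold.

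Among the genes that rose furthest in the DAXX knockout, Grin2c, a subunit of the NMDA glutamate receptor, had 9 reads in wildtype and 359 in the DAXX knockout, a log2 fold of 5.73 (4.79 to 6.87). Ube2l6, the conjugating enzyme for the ubiquitin-like protein ISG15, rose by 4.38 (3.85 to 4.95). Cd200, an immunoglobulin-family surface protein with 2 reads in wildtype, rose by 5.36 (3.45 to 8.44), and Gdpd3, a phosphodiesterase with 0 reads in wildtype, was at least 10.6-fold higher. Tlr2, a receptor for bacterial lipoproteins, rose by 2.95 (2.56 to 3.35), and the transcription factors Bcl11a and Pou4f2 rose by 2.95 (2.35 to 3.60) and 2.72 (2.40 to 3.06). Kbtbd11 rose by 2.81 (2.65 to 2.96), the cholesterol exporter Abca1 by 2.79 (2.59 to 2.99) and Sned1 by 2.80 (2.48 to 3.14). Large falls outside the gene groups included those of Shcbp1, at -4.28 (-4.71 to -3.88), Cr1l, a complement regulator, at -4.29 (-5.11 to -3.57), and the interferon-induced GTPase Gbp2, which had 98 reads in wildtype and 0 in the knockout, at least 24.6-fold lower. Fmr1nb, a cancer-testis gene, went from 131 reads to 0 and was at least 32.9-fold lower.

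**Figure D1:**
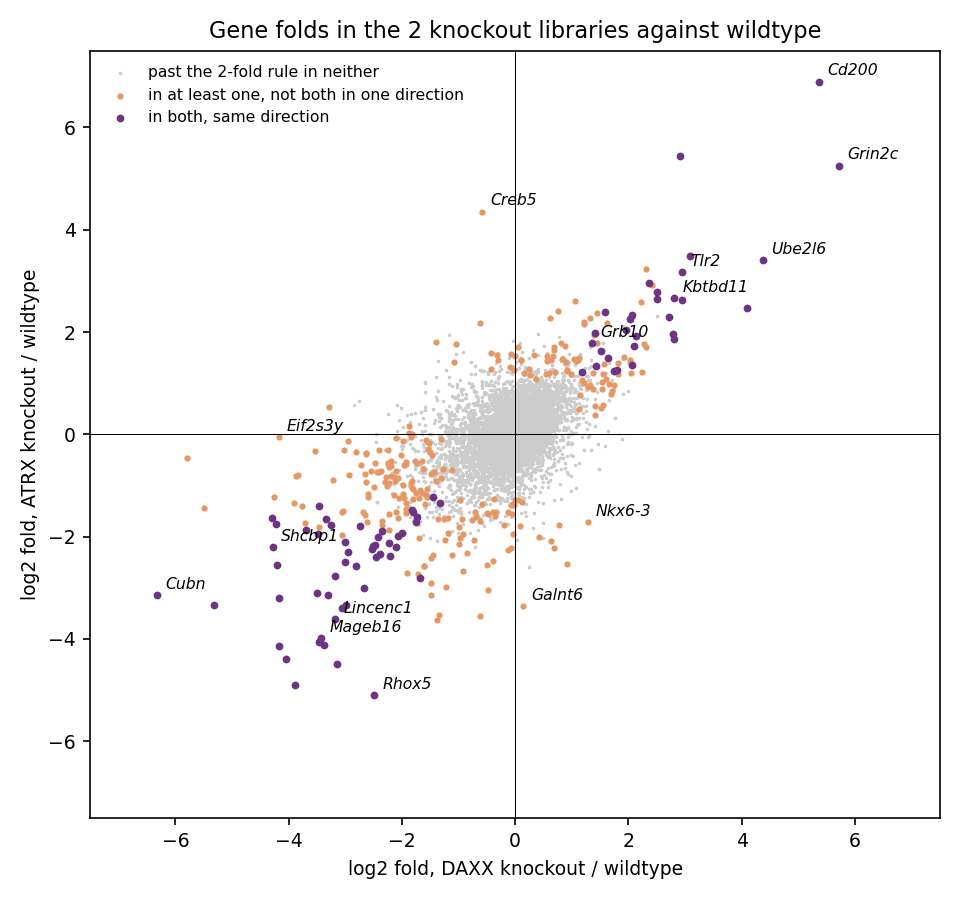
Log2 fold of each gene in the DAXX knockout (horizontal axis) against its log2 fold in the ATRX knockout (vertical axis), both against the same wildtype library, with genes that passed the 2-fold rule coloured. Genes with a count of 0 have no defined fold and are not drawn, and 31 genes rose and 78 fell in both knockouts.

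Of the 19 endoderm genes tested, 13 fell in the DAXX knockout and 0 rose, and the median of -2.32 over the 16 measured members lay at percentile 0 of matched random lists. Gata4, a transcription factor of primitive endoderm, fell by 3.02 (-4.19 to -2.04). Cubn, which encodes the endocytic receptor cubilin, went from 213 reads to 2, a log2 fold of -6.32 (-9.38 to -4.45). The basement membrane collagens Col4a1 and Col4a2 fell by 2.47 (-2.68 to -2.27) and 2.24 (-2.53 to -1.96), and Dab2, an endocytic adaptor, fell by 3.34 (-4.44 to -2.42). Gata6, Sox17, Pdgfra, Lama1, Amn, Srgn, Sparc and Foxq1 were the other members that fell. Markers of trophoblast and of feeder fibroblasts moved with them. Of 11 measured trophoblast genes 4 fell, with a list median of -1.08 at percentile 0. Krt19 fell by 3.46 (-4.32 to -2.70) and Esx1 by 1.81 (-2.57 to -1.12). The others were Rhox6 and Rhox9, which also count in the X-linked list. Among 8 measured fibroblast genes of the 24 listed, the median was -1.36 at percentile 0, and Col1a1, Col1a2, Acta2 and Tagln fell. Tagln had 207 reads in wildtype and 48 in the DAXX knockout, and Col1a1 73 and 14.

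Germline genes gave the next group, with 7 of 30 tested falling and 0 rising, and a median of -0.72 over 29 measured members at percentile 0. Tex19.1, which restrains retrotransposons in germ cells, fell by 1.82 (-2.03 to -1.61), and the meiotic gene Hormad2 by 3.01 (-3.95 to -2.19). Tex11 fell by 2.15 (-2.54 to -1.77) and the ribosomal protein copy Rpl10l by 2.11 (-2.71 to -1.55), with Dazl, Slc25a31 and Piwil2 beside them. In the X-linked multicopy and Rhox list 5 genes fell, and its 6 measured members had a median of -2.97 at percentile 0. Rhox5, a homeobox gene, fell by 2.49 (-3.05 to -1.96), Mageb16 by 3.43 (-3.84 to -3.03), and Xlr3a went from 56 reads to 0, at least 14.04-fold lower. Rhox6 and Rhox9 fell by 3.37 (-5.30 to -1.93) and 3.05 (-4.99 to -1.59). Of the Y-linked genes, Ddx3y, an RNA helicase, went from 775 reads to 0, at least 194-fold lower. Eif2s3y fell by 4.17 (-4.73 to -3.66), Uty by 4.26 (-5.06 to -3.57) and Uba1y, with 1 read left, had a log2 fold of -5.50 (-10.82 to -2.96). The list median was -4.20 at percentile 0, and Kdm5d kept 74.0% of its wildtype level (51.1% to 106%).

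**Figure D2:**
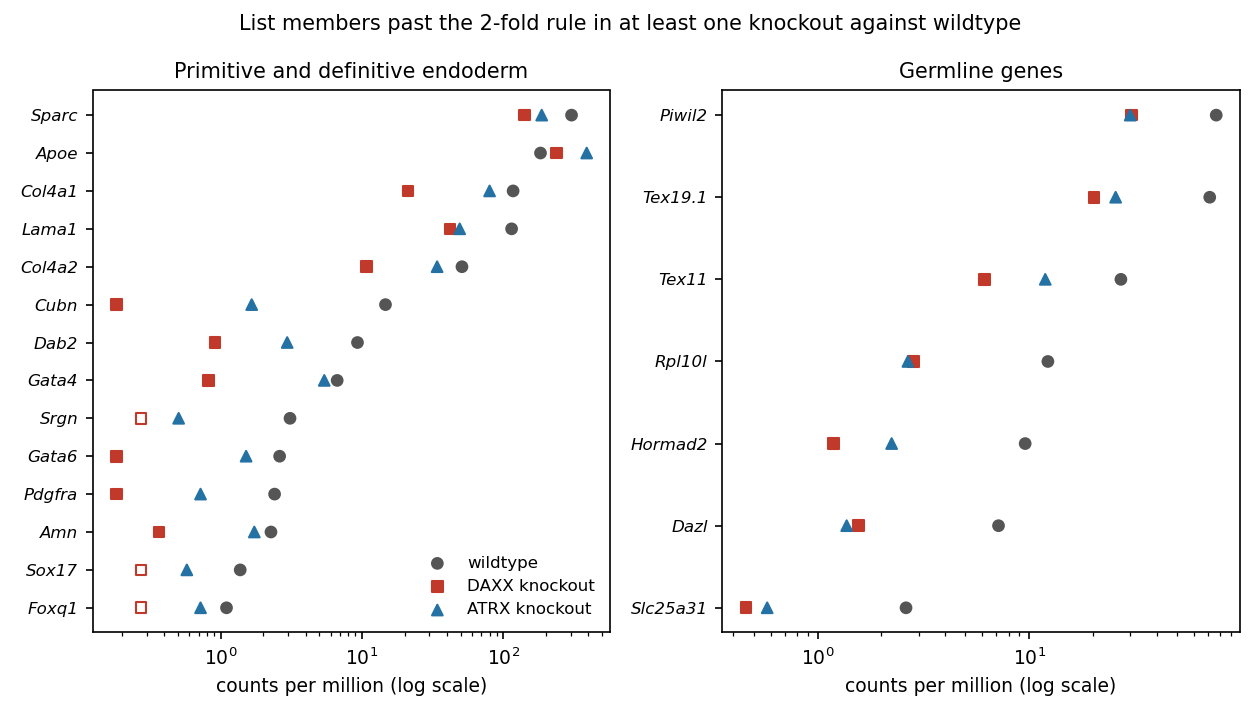
CPM (scaled read counts), on a log axis, of the endoderm and germline genes that passed the 2-fold rule, in the wildtype, DAXX knockout and ATRX knockout libraries. Open squares mark genes with 0 reads, drawn at the floor of 3 counts, and Col4a1 is one of the genes lowest in the DAXX knockout, with 1702, 231 and 1107 reads.

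Pluripotency genes stood higher as a list, by a small amount. None of the 27 measured naive and core pluripotency genes passed the 2-fold rule in the DAXX knockout, and their median of 0.23 lay at percentile 99.98, with Pou5f1 at 0.29 (0.26 to 0.32) and Zfp42 at -0.03 (-0.07 to 0.00). Dnmt3l, a cofactor of de novo DNA methylation, was the silencing factor that fell, by 1.80 (-2.03 to -1.58), while the list of 24 silencing factors had a median of 0.05 at percentile 15.6. Paternally expressed imprinted genes had a median of -0.21 at percentile 1.85, with Igf2 falling by 1.87 (-2.81 to -1.03). Maternally expressed ones had a median of -0.12 at percentile 7.13, where Grb10, a growth-restraining adaptor, rose by 1.35 (1.30 to 1.41). Interferon response genes stood lower, with a median of -0.55 at percentile 0.135 and none past the rule (Stat2 at -0.47, -0.73 to -0.21). Immediate early and stress genes had a median of -0.14 at percentile 1.63, and glycolysis genes a median of -0.01 at percentile 1.27. Clustered protocadherins stood higher, at 0.59 and percentile 100 (Pcdhga12 at 0.91, 0.53 to 1.29). They lie on chromosome 18, where the median of all measured genes was 0.33. Replication-dependent histone genes stood higher at 0.24 and percentile 99.8, with 23 of 65 measured and 0 past the rule. The libraries hold polyadenylated RNA, so histone RNA without a poly(A) tail is not covered by this value.

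Of the 313 zinc finger genes named Zfp that were tested, 5 fell, and the median of 0.05 over 307 measured members lay at percentile 99.0 but became -0.05 when libraries were scaled by total counts. Zfp560 went from 36 reads to 0 and was at least 9.03-fold lower, Zfp600 fell by 2.19 (-2.36 to -2.02), Zfp951 by 1.80 (-2.30 to -1.33) and Zfp534 by 1.43 (-1.55 to -1.30). The remaining lists stood inside the random ones: partners of ATRX and DAXX (median 0.10, percentile 58.0), primed epiblast (-0.06, 37.1), 2-cell-stage genes (-0.57, 10.9, from 5 measured), ancestral pseudoautosomal genes (-0.10, 49.8), p53 targets (0.12, 88.5), telomere and shelterin genes (0.09, 66.0) and primitive streak and mesoderm (0.05, 75.7). The same held for neuroectoderm (0.10, 81.3), X inactivation transcripts (0.22, 90.3), cholesterol synthesis (0.02, 17.8), replication licensing (0.13, 80.01), mitosis (0.04, 6.71) and ribosomal proteins (0.12, 82.1). Igf2 and Esx1 no longer passed the rule when the most abundant transcript stood for the gene, and Igf2 also with counts thinned to the smallest library. The immediate early, paternally expressed and glycolysis lists stood inside the random ones under at least 1 alternative.

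In the ATRX knockout, 92 genes rose and 152 fell by over 2-fold, out of 13230 tested. The same X-linked, germline and imprinted groups held genes that fell, and p53 targets, glycolysis and cholesterol synthesis genes stood higher. Dppa3, a maternal factor that protects DNA methylation in the zygote, fell by 3.55 (-4.65 to -2.62), and Otx2, a transcription factor of primed epiblast, by 2.98 (-3.55 to -2.46). IAP retroviruses rose by 1.27 (1.22 to 1.33), whereas murine leukaemia virus-like elements were at 0.26 (0.09 to 0.43), inside the limit. Here 83.0% of tested genes lay inside 1.5-fold.

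The genes that rose furthest in the ATRX knockout included Cd200, by 6.89 (5.03 to 9.95), Fam159b, with 3 reads in wildtype, by 5.45 (3.87 to 7.75), Grin2c, by 5.26 (4.31 to 6.397), and the transcription factor Creb5, by 4.35 (2.94 to 6.26). Ube2l6 rose by 3.40 (2.87 to 3.99), Tlr2 by 3.17 (2.80 to 3.56), Kbtbd11 by 2.67 (2.52 to 2.82), the ephrin receptor Epha4 by 2.64 (2.49 to 2.79) and the actin regulator Eps8 by 2.38 (2.22 to 2.55). Those that fell furthest included Ddx3y, from 775 reads to 0 (at least 246-fold), Meg3, from 237 to 0 (at least 75.4-fold), Rian, at -6.15 (-7.61 to -5.02), and Fmr1nb, from 131 to 0 (at least 41.7-fold). Rhox5 fell by 5.11 (-6.44 to -4.04), the bicarbonate transporter Slc4a5 by 4.90 (-6.55 to -3.65), Mageb16 by 3.99 (-4.44 to -3.57), and Lincenc1, a long noncoding RNA of ESCs, by 3.61 (-3.90 to -3.33). Xlr3a, with 1 read left, had a log2 fold of -5.74 (-11.07 to -3.20). Klhl4 went from 44 reads to 0 and was at least 13.99-fold lower.

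Of the 30 germline genes tested, 6 fell in the ATRX knockout, with a list median of -0.52 at percentile 0. Dazl, an RNA-binding protein of germ cells, fell by 2.38 (-3.17 to -1.67), Rpl10l by 2.20 (-2.75 to -1.68), Hormad2 by 2.10 (-2.71 to -1.53) and Tex19.1 by 1.48 (-1.66 to -1.30). The X-linked list again had 5 genes that fell and a median of -3.84 at percentile 0. Endoderm genes fell in 4 cases (Dab2, Lama1, Cubn and Srgn) and rose in 1 (Apoe), with a median of -0.64 at percentile 0. Lama1, a laminin chain, fell by 1.22 (-1.35 to -1.09), while Col4a1 was at -0.55 (-0.66 to -0.44) and Gata4 at -0.30 (-0.76 to 0.15). Beside these, trophoblast genes had a median of -0.19 at percentile 18.6, and 3 of the 11 fell. These were Krt19, at -1.40 (-1.79 to -1.03), Rhox6, at -4.13 (-6.45 to -2.51), and Rhox9, at -3.39 (-5.33 to -1.93). Fibroblast genes had a median of -0.14 at percentile 25.9, with Acta2, at 21 reads in wildtype and 2 here, the member that fell. The Y-linked list had a median of -1.24 at percentile 0.1. Ddx3y fell in it, while Eif2s3y kept 96.2% of its wildtype level (86.8% to 107%), Uty 43.0%, Kdm5d 41.7% and Uba1y 36.7%.

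Signalling and stress genes moved in both directions. The p53 targets had a median of 0.58 at percentile 100, and the proapoptotic gene Pmaip1 rose by 1.20 (1.11 to 1.30) and the kinase Plk2 by 1.27 (1.07 to 1.46). The immediate early genes Egr1 and Fos rose by 1.42 (1.24 to 1.61) and 1.46 (1.19 to 1.74), while Trib3 and Chac1, targets of the amino acid response factor ATF4, fell by 1.33 (-1.54 to -1.12) and 2.01 (-2.43 to -1.62), and their list median was 0.16 at percentile 92.8. In the interferon list, Tap1, a peptide transporter of antigen presentation, rose by 1.57 (1.099 to 2.07) and Oas1a fell by 3.63 (-5.56 to -2.19), with a median of -0.02 at percentile 45.9. Glycolysis genes stood higher at 0.37 and percentile 100, with 21 of 22 above 0 and none past the rule (Pkm at 0.47, 0.45 to 0.49). Cholesterol synthesis genes stood higher at 0.25 and percentile 99.9, with 21 of 21 above 0 (Hmgcs1 at 0.36, 0.29 to 0.43). Ribosomal protein genes stood higher at 0.17 and percentile 100. Histone genes did so at 0.37 and percentile 99.8, again from 23 of 65 genes, 0 of them past the rule, and from polyadenylated RNA alone.

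Among imprinted genes, Cdkn1c, a cell cycle inhibitor, rose by 1.32 (1.05 to 1.61), Grb10 by 1.79 (1.74 to 1.84) and Nnat by 2.17 (1.55 to 2.85). Sfmbt2 fell by 2.36 (-2.92 to -1.83) and Usp29 by 2.48 (-4.02 to -1.21). Paternally expressed genes had a median of -0.18 at percentile 1.96 and maternally expressed ones 0.13 at percentile 85.6. AU018091, from the list of 2-cell-stage genes, fell by 2.56 (-2.77 to -2.35), with a list median of -0.25 at percentile 22.7. Il3ra, a cytokine receptor gene of the ancestral pseudoautosomal region, fell by 2.09 (-3.01 to -1.27), with a list median of -0.57 at percentile 3.62. Silencing factors stood lower, at -0.08 and percentile 1.12, with Trim28 at -0.37 (-0.39 to -0.34). Neuroectoderm genes stood lower at -0.36 and percentile 0.57, a direction that turned to 0.13 with the most abundant transcript of each gene. Genes named Zfp stood lower at -0.05 and percentile 0.41, where Zfp36 rose by 1.45 (1.16 to 1.76) and Zfp560 fell by 3.10 (-5.05 to -1.62).

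The other lists stood inside the random ones in the ATRX knockout: naive and core pluripotency (-0.04, percentile 6.71), primed epiblast (-0.23, 2.72), partners of ATRX and DAXX (0.06, 60.3), telomere and shelterin genes (0.05, 58.2), primitive streak and mesoderm (0.12, 79.2) and X inactivation transcripts (-0.07, 38.5). The same was true of replication licensing (0.13, 92.9), mitosis (0.14, 94.9) and clustered protocadherins (0.20, 91.2). Only 3 Hox genes were measured, with medians of 0.48 in the DAXX knockout, 0.07 in the ATRX knockout and 0.55 between the knockouts. Of 9 globin genes listed, which include known targets of ATRX in red cells, 0 were measured, and 0 mitochondrially encoded genes were among the sequences counted. Over all 3 comparisons, 44 of 87 list percentiles stood apart, 24 lower and 20 higher. For lists of randomly drawn genes 4.35 are due by chance. Members of a list can vary together, and the 3 comparisons reuse the same libraries. The 4.35 is therefore not the number that unchanged genotypes would give for these lists. In the ATRX knockout, Tap1, Krt19 and Acta2 no longer passed the rule with thinned counts, Cdkn1c with total counts, and Tap1, Cdkn1c and Dab2 with the most abundant transcript. The histone list lost its place with the most abundant transcript, and the silencing factors theirs against unmatched random lists.

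**Figure D3:**
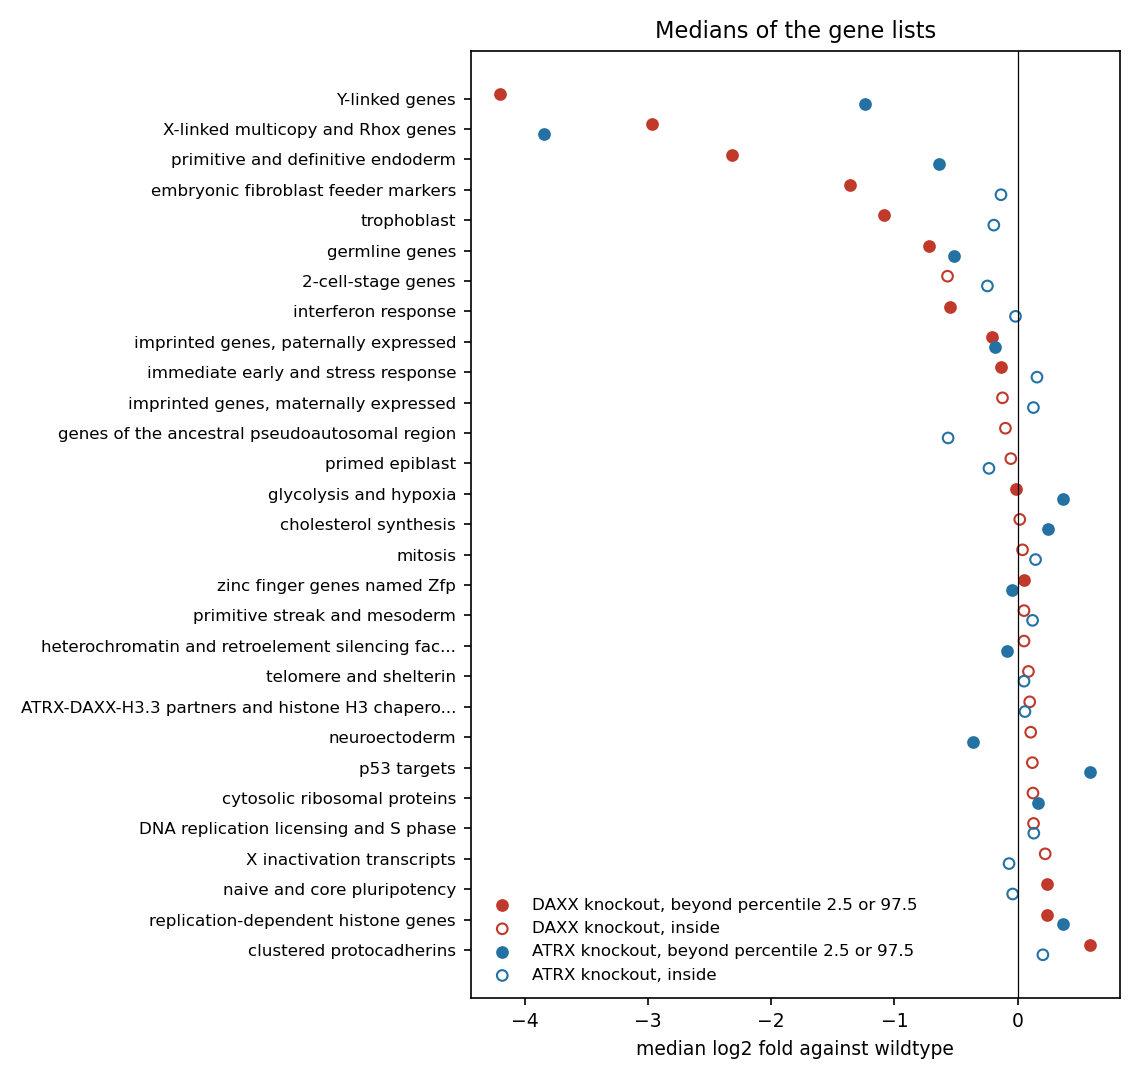
Median log2 fold of each gene list in the DAXX knockout and the ATRX knockout against wildtype, with filled symbols for lists that stood apart from matched random lists. Y-linked, X-linked and endoderm lists lie farthest to the left in the DAXX knockout, with medians of -4.20, -2.97 and -2.32.

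Both knockouts shared more changes in one direction than independent lists of their sizes would. Grin2c, Ube2l6, Cd200, Gdpd3, Kbtbd11, Tlr2, Pou4f2, Bcl11a, Epha4 and the formin gene Fmn2 led 31 genes that rose in both, against 0.398 for independent lists. Ddx3y, Meg3, Rian, Fmr1nb, Xlr3a, Mageb16, Lincenc1, Slc4a5, Cubn and Magohb, a component of the exon junction complex, led 78 genes that fell in both, against 2.38. Magohb fell by 4.17 (-5.50 to -3.09) in the DAXX knockout and 4.15 (-5.30 to -3.19) in the ATRX knockout. Of the 78 genes, 13 genes (16.7%) lie on the X chromosome, which holds 3.36% of the genes tested in both. The homeobox gene Nkx6-3 was the one gene with opposite calls, rising by 1.28 (1.04 to 1.53) in the DAXX knockout and falling by 1.72 (-2.15 to -1.31) in the ATRX knockout, and its rise did not pass the rule with total counts or thinned counts.

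Both comparisons used the same wildtype library. With 3 unchanged libraries simulated at the dispersion estimated from these libraries, the shared genes had a median of 16 higher (8 to 26) and 13 lower (5 to 21), and with Poisson noise a median of 0 in each direction. In the DAXX knockout alone the dispersed simulation called a median of 71 genes higher (49 to 94) and 65 lower (46 to 81), and in the ATRX knockout 72 higher (54 to 93) and 75 lower (52 to 94). The 64 and 92 genes that rose thus lay inside the range of unchanged libraries, and the 204 and 152 that fell lay above it. That dispersion also takes in any effect of genotype. The log2 folds of the 2 knockouts correlated across genes at 0.604, against 0.490 in the dispersed and 0.458 in the Poisson simulation, and genes are not independent replicates. Their covariance was 0.173, against 0.120 and 0.0176. The simulated comparisons also shared 1 wildtype library, so sharing at the simulated noise is already part of their values. A wildtype clone that itself stands apart may add to the excess, and 1 library cannot be split to test this. Set apart from both others, the wildtype library had 109 genes, which are by definition the 31 and 78 genes shared by the knockouts. The DAXX knockout had 37 (3 higher and 34 lower) and the ATRX knockout 39 (18 higher and 21 lower). For wildtype, the DAXX knockout and the ATRX knockout, the dispersed simulation gave medians of 29 (17 to 42), 28.5 (18 to 42) and 30 (19 to 45).

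The 2 knockouts were then compared with each other, where 100 genes were higher and 47 lower in the ATRX knockout than in the DAXX knockout, out of 12991 tested. Endoderm, Y-linked, trophoblast and fibroblast genes, p53 targets, interferon and glycolysis genes stood higher in the ATRX knockout, and pluripotency and primed epiblast genes stood lower. Creb5 was higher by 4.94 (3.04 to 8.01), the axonal kinesin Kif1a by 2.81 (2.41 to 3.24), the metal transporter Slc11a1 by 2.79 (2.17 to 3.48) and Clic6 by 3.20 (2.01 to 4.70). Lower in the ATRX knockout were the glycosyltransferase gene Galnt6, at -3.50 (-4.03 to -3.002), Ttn, at -3.44 (-3.82 to -3.08), Nkx6-3, at -3.01 (-3.41 to -2.62), and Dppa3, at -2.93 (-4.06 to -1.95). Of all tested genes, 83.8% lay inside 1.5-fold.

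Endoderm genes had a median of 1.62 between the knockouts at percentile 100, or 1.56 with genes at 0 counts set to their bound. Gata4 was higher in the ATRX knockout by 2.72 (1.72 to 3.90), Cubn by 3.18 (1.16 to 6.31), Col4a1 by 1.92 (1.71 to 2.13) and Col4a2 by 1.65 (1.36 to 1.96), and Gata6 was the fifth member past the rule. Beside them, trophoblast genes had a median of 0.61 at percentile 99.0, with Krt19 higher by 2.05 (1.25 to 2.96) and Esx1 by 1.82 (1.13 to 2.58). Fibroblast genes had a median of 0.74 at percentile 99.6, with Col6a2, at 2 and 27 reads, higher by 3.41 (1.42 to 6.53). The Y-linked list had a median of 2.99 at percentile 100, and Eif2s3y was higher by 4.12 (3.61 to 4.68), Uty by 3.05 (2.33 to 3.86) and Uba1y by 4.05 (1.41 to 9.42). Shcbp1 and Cr1l, which fell in both knockouts, were higher in the ATRX knockout by 2.07 (1.64 to 2.53) and 2.66 (1.90 to 3.51), and Vat1l, at 2 and 36 reads, by 3.83 (1.87 to 6.93).

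Pluripotency genes had a median of -0.25 at percentile 0 and primed epiblast genes -0.37 at percentile 0.07, with Gbx2 lower by -1.24 (-1.38 to -1.10) and Otx2 by -1.76 (-2.38 to -1.17). The p53 targets had a median of 0.58 at percentile 100, led by Plk2 at 1.70 (1.46 to 1.95), and interferon genes 0.54 at percentile 99.9, led by Tap1 at 1.64 (1.101 to 2.21). Glycolysis genes had a median of 0.45 at percentile 100, cholesterol synthesis genes 0.16 at percentile 99.9, mitosis genes 0.12 at percentile 99.98 and ribosomal proteins 0.03 at percentile 99.95. Bmp7 and the Nodal antagonist Lefty1 were higher in the ATRX knockout than in both other libraries, with 1.65 (1.32 to 2.00) and 1.27 (1.12 to 1.41) against the DAXX knockout. Egr1 was higher by 2.505 (2.23 to 2.79) and Fos by 1.76 (1.43 to 2.10), and Chac1 was lower at -2.44 (-2.85 to -2.04) and Trib3 at -1.46 (-1.68 to -1.24). Their list stood inside the random ones (median 0.08, percentile 85.9).

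Of the imprinted genes, maternally expressed ones had a median of 0.43 at percentile 99.96, led by Cdkn1c at 1.42 (1.105 to 1.74). Paternally expressed ones had a median of -0.21 at percentile 0.465, although Dlk1 and Igf2 were higher, by 2.54 (1.19 to 4.25) and 1.89 (1.05 to 2.84). The X-linked list had a median of -0.42 at percentile 1.75, with Rhox5 lower at -2.62 (-4.04 to -1.43). Clustered protocadherins, at -0.40 and percentile 0.26, lie on chromosome 18, whose median was -0.29. Genes named Zfp had a median of -0.09 at percentile 0, with Zfp600 higher by 1.67 (1.496 to 1.85) and Zfp532 lower at -1.29 (-1.40 to -1.18). AU018091 was lower at -2.06 (-2.29 to -1.84) and Il3ra at -2.72 (-3.63 to -1.91), while their lists had medians of 0.32 (percentile 78.8) and 0.00 (percentile 41.0). The germline list, where Tex15 was higher by 1.52 (1.19 to 1.87), had a median of 0.13 at percentile 86.1. The remaining lists were inside: partners of ATRX and DAXX (-0.01, 71.0), silencing factors (-0.10, 9.89), telomere genes (-0.07, 20.2), mesoderm (0.37, 91.0), neuroectoderm (0.04, 58.7), X inactivation (-0.34, 5.06), replication licensing (-0.04, 49.8) and histone genes (0.08, 38.2). With the most abundant transcript, Tap1, Esx1, Igf2, Dlk1, Rhox5, Col6a2, Uty and Uba1y no longer passed the rule, and the interferon list stood inside the random ones. Without a filter on low counts the Y-linked, trophoblast and X-linked lists did so too, and so did the mitosis and ribosomal protein lists against unmatched lists and the protocadherins with folds centred on their chromosome.

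Retroviral and other repeat sequences were counted in the same libraries. IAP elements, which are long terminal repeat retroviruses of the mouse genome, had 3549 reads in wildtype, 9500 in the DAXX knockout and 8181 in the ATRX knockout, and the difference between the knockouts was -0.56 (-0.60 to -0.52). Murine leukaemia virus-like elements had 559, 1897 and 638 reads and were lower in the ATRX knockout than in the DAXX knockout, at -1.91 (-2.05 to -1.78). The gamma (major) satellite rose from 12 reads to 39 in the DAXX knockout, by 2.11 (1.15 to 3.18), and had 10 in the ATRX knockout, at -0.20 (-1.56 to 1.14). ETn and MusD elements, the most abundant family, were at 0.61 (0.60 to 0.63) in the DAXX knockout and 0.41 (0.40 to 0.43) in the ATRX knockout. LINE-1 elements were at 0.35 (0.32 to 0.37) and -0.50 (-0.53 to -0.48), and MERVL, a retrovirus of 2-cell embryos, at -0.28 (-0.37 to -0.18) and -0.62 (-0.71 to -0.52).

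The other families stayed inside the limit in both knockouts. The DAXX and ATRX values were 0.07 and -0.39 for MaLR elements, 0.39 and -0.48 for MMERVK10, 0.19 and -0.38 for VL30, 0.41 and -0.10 for B1 and -0.28 and -0.75 for B2 elements. All repeats together were at 0.59 (0.58 to 0.60) in the DAXX knockout and 0.21 (0.20 to 0.22) in the ATRX knockout. Of single consensus sequences, 8 of 118 tested rose and 0 fell in the DAXX knockout, 3 of 109 rose and 1 fell in the ATRX knockout, and between the knockouts 0 of 112 were higher and 4 lower in the ATRX knockout. The retroelement list set beforehand matched 397 of these sequences, 72 of them measured, with medians of 0.20, -0.52 and -0.72. Polyadenylated RNA counted on consensus sequences does not show which genomic copies were transcribed.

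**Figure D4:**
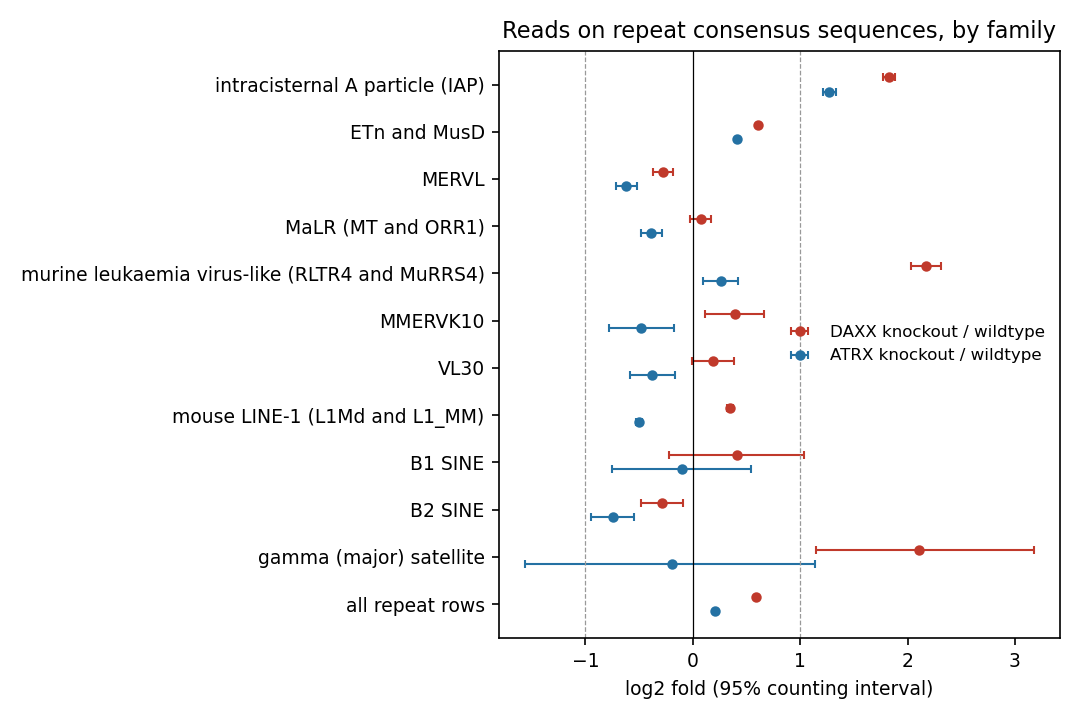
Log2 folds of repeat families in the DAXX knockout and the ATRX knockout against wildtype, with bars for the 95% counting interval and dashed lines at 2-fold. IAP elements lie beyond 2-fold in both knockouts (1.83 and 1.27), and murine leukaemia virus-like elements in the DAXX knockout (2.17).

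Whole chromosomes also differed between the libraries. On chromosome 11 the median log2 fold of measured genes was -0.24 (-0.26 to -0.22) in the DAXX knockout and -0.23 (-0.26 to -0.20) in the ATRX knockout, and 0.02 between the knockouts. On chromosome 18 it was 0.33 (0.29 to 0.35) in the DAXX knockout and 0.07 in the ATRX knockout. Medians of the other autosomes ran from 0.00 to 0.09 in the DAXX knockout and from -0.01 to 0.07 in the ATRX knockout. Grin2c and Grb10, which rose in both knockouts, and Hormad2, Tex19.1 and Krt19, which fell in both, lie on chromosome 11. Without the genes of chromosomes 11, 18 and Y, which were chosen after these medians were seen, 57 genes rose and 170 fell in the DAXX knockout, 81 rose and 129 fell in the ATRX knockout, and 88 were higher and 39 lower between them.

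**Figure D5:**
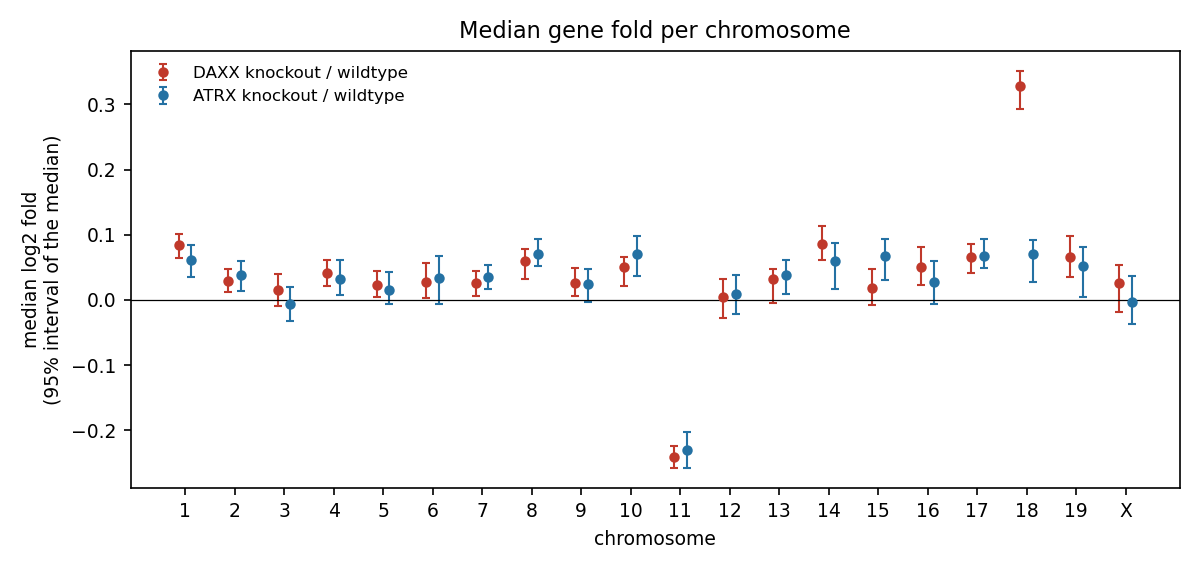
Median log2 fold of measured genes on each autosome and the X chromosome in the DAXX knockout and the ATRX knockout against wildtype, with the 95% interval of the median. Chromosome 11 lies below the other autosomes in both knockouts (-0.24 and -0.23), and chromosome 18 above them in the DAXX knockout (0.33).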

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

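The tests of the Y-linked genes and the test of fibroblast collagens were chosen after the results were seen, and the others were written down before their results were seen.

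Nkx6-3 went opposite ways in the 2 knockouts, with a log2 fold of 1.28 in the DAXX knockout and -1.72 in the ATRX knockout. Medians of the glycolysis list were -0.0127 and 0.368, but in the DAXX knockout 11 members lay above 0 and 11 below, so that no direction is given there. Medians of the genes named Zfp were 0.0472 and -0.0465, and the first turned to -0.0453 with total counts, so their direction in the DAXX knockout depends on the scaling. With 1 library for each genotype these differences were not tested.

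Chromosome 11 had lower medians in both knockouts and chromosome 18 a higher one in the DAXX knockout, shifted by -0.282, -0.271 and 0.287 from the other autosomes. The tables argue against GC content, since genes of other autosomes matched on GC were shifted by 0.00961 and 0.0211 for chromosome 11 and by -0.0065 for chromosome 18. The shift was on the chromosome's side in 100% of the 10 Mb windows with at least 20 genes. These were 12 of 12 for chromosome 11 in each knockout and 8 of 8 for chromosome 18. The shift was thus not confined to a short stretch, as a copy-number difference of most of the chromosome would give. These chromosomes were picked for their medians, and the size of the shift was not compared with that of a gained or lost copy. Because both knockouts were lower on chromosome 11 and did not differ from each other there (0.02), the difference may lie in the wildtype clone, and DNA was not analysed here. The effect of genotype itself stays open and untested, as 1 clone stood for each.

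Eif2s3y, Uty and Uba1y kept a common share of 5.27% of their wildtype level in the DAXX knockout, inside the interval of each. Loss of the Y chromosome from most cells would give a common share for these 3 genes. They were grouped because they were low, and Uba1y, with 1 read left, had a wide interval (0.0552% to 12.8%). The common share therefore weighs little. At that common share 30.7 Ddx3y reads would be left where 0 were counted. This holds only if the reads left on the 3 genes came from the Y chromosome. That was not checked, so the test does not decide whether loss of the chromosome accounts for Ddx3y. Such loss does not account for Kdm5d, which kept 74.0% (51.1% to 106%), if its reads came from the Y chromosome. In the ATRX knockout, where Eif2s3y kept 96.2%, Uty 43.0%, Kdm5d 41.7% and Uba1y 36.7%, Ddx3y was also at 0 reads, and loss of the chromosome does not account for it, since 311.6 reads would be left at the common share of the last 3. Loss from part of the cells stays open there for Uty, Kdm5d and Uba1y, against which Eif2s3y stands as 1 gene. A deletion of Ddx3y carried by both clones may play a part, as may reads of X-linked copies placed on Kdm5d, Eif2s3y, Uty or Uba1y. Like a direct effect of genotype, these were not tested.

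Endoderm genes were lower in the DAXX knockout, with a median of -2.32. Fibroblast genes were lower as well, with a median of -1.364 at percentile 0 and 7 of 8 measured members below 0, so some feeder cells in the wildtype library stay open, but the tables argue against them as the whole of the change, since Col1a1, Col1a2 and Col3a1 together lost 5.81% as much CPM as Col4a1. A smaller share of endoderm-like cells cannot be told apart from a change within the stem cells. A second endoderm list lay at percentile 21.6, with 7 of 11 measured members below 0, which decides for neither. That list was first meant to argue against fewer such cells if it stood inside the random ones, but members such as Nid2 were at 402 CPM in wildtype and 408 CPM in the DAXX knockout, a level that would hide a small share of cells, while Pth1r, Cited1 and Vil1 fell. An effect of DAXX loss on these genes may be present and was not separated from either.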

How the results depend on the processing

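Leaving out chromosomes 11, 18 and Y and rescaling the repeat families were alternatives chosen after the data were seen, and the other alternatives were set beforehand. No paired analysis was possible because each genotype had 1 library. The direction of all 3 comparisons of counts, higher against lower, held under every alternative, and no scaling moved the split by over 10 points. Other settings brought it nearer to even. In the ATRX knockout 37.7% of calls were rises, against 47.3% with a filter of 5 CPM and 48% with a fold limit of 1.5. In the DAXX knockout these shares were 23.9%, 33.3% and 30.9%. Calls of named genes were followed under part of the alternatives. Other fold limits, the fold without its interval and leaving out chromosomes 11, 18 and Y were not applied to them. Atrx and Daxx were counted apart. Among the other named genes, 0 of the calls reversed, 58 were lost and 7 gained, most losses being genes under a filter of 5 CPM. List medians were counted once for each list, comparison and alternative that was applied to the lists. Of these, 20 left the outer percentiles, 22 entered them and 2 reversed. Another 18 changed sign while inside the random lists, and the rest kept their standing. IAP elements kept log2 folds from 1.74 to 1.83 in the DAXX knockout and from 1.20 to 1.27 in the ATRX knockout.

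With a fold limit of 1.5, 184 genes rose and 412 fell in the DAXX knockout, 336 rose and 364 fell in the ATRX knockout, and 325 were higher and 193 lower between the knockouts. The knockouts then shared 99 higher and 171 lower genes, and 270 genes set wildtype apart, 120 the DAXX knockout and 177 the ATRX knockout. With a limit of 4, the counts were 16 and 50, 17 and 37, and 8 and 5, with 10 and 20 shared and 30, 3 and 3 apart. With the fold alone they were 208 and 796, 327 and 607, and 604 and 279, with 91 and 332 shared and 423, 325 and 257 apart. These changes follow from the limits themselves. A filter of 5 CPM tests fewer genes. It left 54 rises and 108 falls in the DAXX knockout, and 79 rises and 88 falls in the ATRX knockout. Between the knockouts 64 genes were higher and 38 lower. Shared falls numbered 42, and 69 and 23 genes set wildtype and the DAXX knockout apart.

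With total counts the median of all genes moved to -0.07 in the DAXX knockout and -0.05 in the ATRX knockout, from 0.03 and 0.02. Chromosome 11 then had medians of -0.3345, -0.2988 and 0.04 in the DAXX knockout, the ATRX knockout and between them, chromosome 18 had 0.2346 and 0.0013 in the knockouts, Atrx in the DAXX knockout was at -0.0407, and the Zfp list in the DAXX knockout reversed to -0.0453. Without a filter on low counts, chromosome 11 had -0.2793 and -0.2601 in the knockouts and chromosome 18 had 0.268 in the DAXX knockout and -0.238 between the knockouts. With the most abundant transcript of each gene, the neuroectoderm list in the ATRX knockout reversed to 0.1267, and the cause was not tested. Depth limits genes with few reads most, since the floor of 3 counts bounds every fall to 0 and changes near 2-fold were mostly missed in simulation.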

Other observations

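The stretch of chromosome 4 and the repeat sequences singled out here were chosen after their values had been seen.

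Neighbouring genes on chromosome 4, in a cluster that holds the zinc finger genes Rex2, Zfp534 and Zfp600 and many predicted genes, were low together in the DAXX knockout. Of 13 measured genes between 145510759 and 147809788 (GRCm38), 13 were below 0 and 8 fell by over 2-fold, with a median log2 fold of -1.43 and a range from -2.49 to -0.51. Rex2 fell by 2.20 (-2.41 to -1.98) and Zfp600 by 2.19 (-2.36 to -2.02). In the ATRX knockout 13 were below 0 with a median of -0.58 and 0 passed the rule, and between the knockouts the median was 0.69 with 5 higher in the ATRX knockout. Within 2 Mb beyond the end of the cluster, 38 genes had a median of 0.06 in the DAXX knockout, and 5 genes within 2 Mb before its start had -0.39. Genes of such clusters can be near-identical copies that exchange reads, so their single values are uncertain.

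Single repeat sequences did not all follow their family. The IAP internal sequence IAPEZI was at 2.00 in the DAXX knockout and 1.43 in the ATRX knockout. The long terminal repeat RLTR1IAP had 17 reads in wildtype, 158 in the DAXX knockout and 107 in the ATRX knockout, log2 folds of 3.63 and 2.72. IAPLTR4_I, with 30 reads in wildtype, was at -0.911 and -0.839. Of the LINE-1 sequences, L1MdA_I was at -0.173 in the DAXX knockout and L1MdGf_I at 0.976. These sequences were chosen after their values were seen.

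Fndc3c1, on the X chromosome, fell by 3.53 (-5.86 to -1.89) in the DAXX knockout, to 3 reads, and was at -0.33 (-1.004 to 0.34) in the ATRX knockout. Erdr1, whose copies are placed on the sex chromosomes, was at 0.63 (0.48 to 0.78) and 1.03 (0.90 to 1.17). Tsix, the antisense transcript of the X inactivation centre, was at 0.65 (0.20 to 1.097) and 0.72 (0.30 to 1.14). The neuronal tubulin regulator Stmn2 was at 0.90 in both knockouts (0.83 to 0.97 and 0.84 to 0.97), and the signalling gene Bmp4 at 0.93 (0.73 to 1.13) in the DAXX knockout and 0.12 (-0.09 to 0.34) in the ATRX knockout.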
